A study of Mus musculus with 2 samples.

How the data were processed

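Bulk TCR sequencing of thymic iNKT cells was analysed from 2 mouse samples, 1 wild type and 1 Prkd2/3-deficient, grouped by the genotype in their labels. Per the labels' protocols, thymocytes binding a CD1d tetramer loaded with alpha-galactosylceramide were enriched on magnetic beads and sorted as TCR beta-positive, tetramer-positive, propidium iodide-negative cells. RNA from 10000 to 100000 cells was reverse transcribed and amplified with a SMARTer mouse TCR a/b kit, in 21 cycles of a first and 24 cycles of a second PCR, per the labels' protocols.

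Each deposited file lists clones, 1 per CDR3 nucleotide sequence, with the V, D, J and C segments assigned to it. Per the file headers, the values are a clone count, the number of reads, and a clone fraction. The deposited fraction equalled the count over the library total of all chains in every clone of both files, and counts were used for all shares. The column names are those of a MiXCR export, per the file headers, while the version, germline library, quality filters and any subsampling of reads are not given in the sources used here. The names of both deposited files carry the same round number, which could mark a subsample of reads; no header states this, so the depths given are those of the deposited lists. The files hold no molecular identifiers.

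A clone was assigned to TRA or TRB by its V and J segments, taking the first segment named, and was productive when its CDR3 held no frame break or stop. The invariant chain was planned as TRAV11 or TRAV11D, first named, joined to TRAJ18. Because an abundant wild-type clone with an identical V sequence was called TRAV11N first, a call that lists TRAV11 or TRAV11D among its segments was also counted as invariant, a choice made after the data were seen. Both values are given, and the wider rule defines the non-invariant chains. Of 194 V and J segment names in the files, 193 matched a gene symbol of the RefSeq annotation of GRCm38.p6, which was used only for names and for the order of TRAJ segments. No genome build is given in the sources used here, so no coordinates are printed.

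Shares are given with exact (Clopper-Pearson) 95% binomial intervals, differences between shares with Newcombe intervals, and ratios of small counts with exact conditional intervals. The difference of mean CDR3 lengths has a normal 95% interval from the SD over clonotypes, which are not replicates. A count of 0 was taken to allow 3 counts of the total. Richness, Shannon entropy, inverse Simpson index and clonality of productive TRB clonotypes were computed after thinning to 24133 reads without replacement, in 100 seeded draws. Clonotypes were shared when V, J and CDR3 were identical. With 1 library per genotype there is no replicate, so no test was run. Calculations used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and plots matplotlib 3.10.9.

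The functions were tested on simulated data. In draws from the real TRBV shares, the exact interval held the true share in 95.2% of 480 wild-type and 94.4% of 480 Prkd2/3-deficient simulated values. The thinned clonotype ratio was 1.00 times its expected value, and 100% of 200 planted copies with 1 mismatch were merged. The simulated clones were equally abundant, unlike those of the libraries. The planted copies came from clones of 200 reads, while only 4 wild-type productive TRB clonotypes had over 20 reads. These checks therefore cover the functions, not the richness or the errors of these libraries.

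Before the data were examined, the listed segments, the comparisons, 47 of the 65 alternatives and the naming rule were fixed. The other 18 alternatives, and the tests of explanations that the closing section names as chosen later, were added after the data were seen. Every listed segment or chain is named: TRAV11, TRAV11D, TRAJ18, TRBV13-1, TRBV13-2, TRBV13-3, TRBV29, TRBV1, TRAV1-TRAJ33 and TRAV13 family-TRAJ50. In addition a TRBV, TRBJ, non-invariant TRAV or non-invariant TRAJ segment is named when it had at least 1% of its reads in either library, a difference of at least 1.5-fold, intervals that do not overlap, and the same direction with each clonotype counted once, up to the 8 largest ratios of each kind. The 5 most abundant TRB clonotypes of each library, and any over 1% in both, are named too. TRBV17 was named after its values were seen.

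Alternatives counted each clonotype once, included non-productive rearrangements, left out single-read clonotypes, left out calls with several segments, left out the most abundant clonotype, used amino acid in place of nucleotide CDR3, merged clonotypes 1 mismatch from one with at least 20 times the reads, or used unthinned reads. D segment calls and constant region calls were not analysed here.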

Results

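T cell receptor transcripts of thymic invariant natural killer T (iNKT) cells were profiled in mice of 2 genotypes, wild type and Prkd2/3-deficient, with 1 library each. Prkd2 and Prkd3 encode protein kinase D isoforms, serine/threonine kinases that act downstream of antigen receptor signalling, and the deletion carries the label ΔCD4 in the design text. iNKT cells are T cells that recognise glycolipids on CD1d through a nearly fixed TCR alpha chain, TRAV11 joined to TRAJ18, paired with beta chains of few V segments. The cells were sorted as TCR beta-positive cells binding a CD1d tetramer loaded with alpha-galactosylceramide. The wild-type library held 130786 reads in 20442 clonotypes and the Prkd2/3-deficient library 189886 reads in 7090 clonotypes, where a clonotype is 1 CDR3 nucleotide sequence with its V and J segments. Of these, 105589 wild-type and 119964 Prkd2/3-deficient reads were TRA, and 25193 and 69856 were TRB. With 1 library per genotype, no difference below has a replicate check and no test was made. The exact binomial 95% intervals given in brackets cover counting error only, and because reads carry no molecular identifiers in these files, they are not independent molecules.

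The alpha chain was examined first, as it defines the sorted population. Both libraries were dominated by TRAV11-TRAJ18. By the first V segment named in each call, the rule set before the data were examined, TRAV11 or TRAV11D joined to TRAJ18 took 71.4% (71.1 to 71.7) of the 97266 productive TRA reads in wild type and 97.5% (97.4 to 97.5) of the 108722 in the Prkd2/3-deficient library. The wild-type shortfall came almost entirely from 1 clonotype of 25835 reads called TRAV11N first. Its assembled V sequence was identical to that of the most abundant TRAV11 clonotype, and the same CDR3 nucleotide sequence was called TRAV11 in the other library. When calls that list TRAV11 or TRAV11D among several segments were counted, a rule chosen after seeing the data, the shares were 98.0% (97.9 to 98.1) in wild type and 97.5% (97.4 to 97.5) in the Prkd2/3-deficient library, a difference of -0.509 percentage points. The wider rule defines the invariant and non-invariant chains in the paragraphs that follow, except where the first segment named is stated.

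The germline-like invariant CDR3, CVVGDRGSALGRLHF, made up 97.6% (97.5 to 97.7) of TRAV11-TRAJ18 reads in wild type and 96.5% (96.4 to 96.6) in the Prkd2/3-deficient library. It was encoded by 6 nucleotide sequences in wild type and 4 in the Prkd2/3-deficient library. All 4 glycine codons were used at the V-J junction, in the same rank order: GGC in 41.9% and 38.7% of these reads, GGG in 27.8% and 28.4%, GGA in 17.2% and 19.1%, and GGT in 13.1% and 13.8%.

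Beta chain use was compared next, for the segments known to be enriched among mouse iNKT cells. TRBV13-1, TRBV13-2 and TRBV13-3 (the V beta 8 family), TRBV29 (V beta 7) and TRBV1 (V beta 2) together took 94.2% (93.9 to 94.5) of 24133 productive TRB reads in wild type and 92.1% (91.9 to 92.3) of 66759 in the Prkd2/3-deficient library. TRBV13-2, the main iNKT beta segment, was the most used in both, at 35.5% (34.9 to 36.2) in wild type and 34.6% (34.2 to 34.9) in the Prkd2/3-deficient library. TRBV29 followed at 23.6% (23.0 to 24.1) and 24.4% (24.1 to 24.7), and TRBV13-1 at 18.2% (17.7 to 18.7) and 20.1% (19.8 to 20.5). TRBV13-3 had 8.70% (8.35 to 9.06) of wild-type reads against 6.91% (6.72 to 7.11), and TRBV1 8.24% (7.90 to 8.60) against 6.08% (5.90 to 6.26). Without the most abundant clonotype of each library, the gap in the 5 segments together was -1.11 percentage points in place of -2.13. With single-read clonotypes left out, the direction by reads turned for TRBV13-2, to 32.2% in wild type against 34.4%, and for TRBV29, to 25.7% against 24.5%.

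Counting each clonotype once changed the direction for 3 of the 5 segments. TRBV13-2 then took 38.6% (37.8 to 39.4) of 14236 wild-type clonotypes and 44.7% (43.3 to 46.1) of 5004 Prkd2/3-deficient clonotypes. TRBV29 took 21.6% (21.0 to 22.3) and 19.2% (18.1 to 20.3), and TRBV13-1 16.6% (16.0 to 17.3) and 13.9% (12.9 to 14.9). TRBV13-3 and TRBV1 stayed lower in the Prkd2/3-deficient library, at 8.13% against 6.22% and at 9.11% against 8.17% of clonotypes. The clonotype shares depend on how completely each library was sampled, and the libraries differed in this: 59.7% of wild-type and 15.7% of Prkd2/3-deficient productive TRB clonotypes had a single read. When the Prkd2/3-deficient library was thinned to the wild-type number of reads per clonotype, an alternative added after the data were seen, each of these 3 segments took the direction it had by all reads. Over 100 draws TRBV13-2 then had a mean of 38.1% (range 36.3 to 39.7), TRBV29 23.2% (21.9 to 24.6) and TRBV13-1 17.6% (16.5 to 19.0) of Prkd2/3-deficient clonotypes. The ranges of TRBV13-2 and TRBV13-1 included the wild-type share. Such thinning draws a clonotype share towards the share by reads, so the turn in direction is not independent of the read values.

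**Figure D1:**
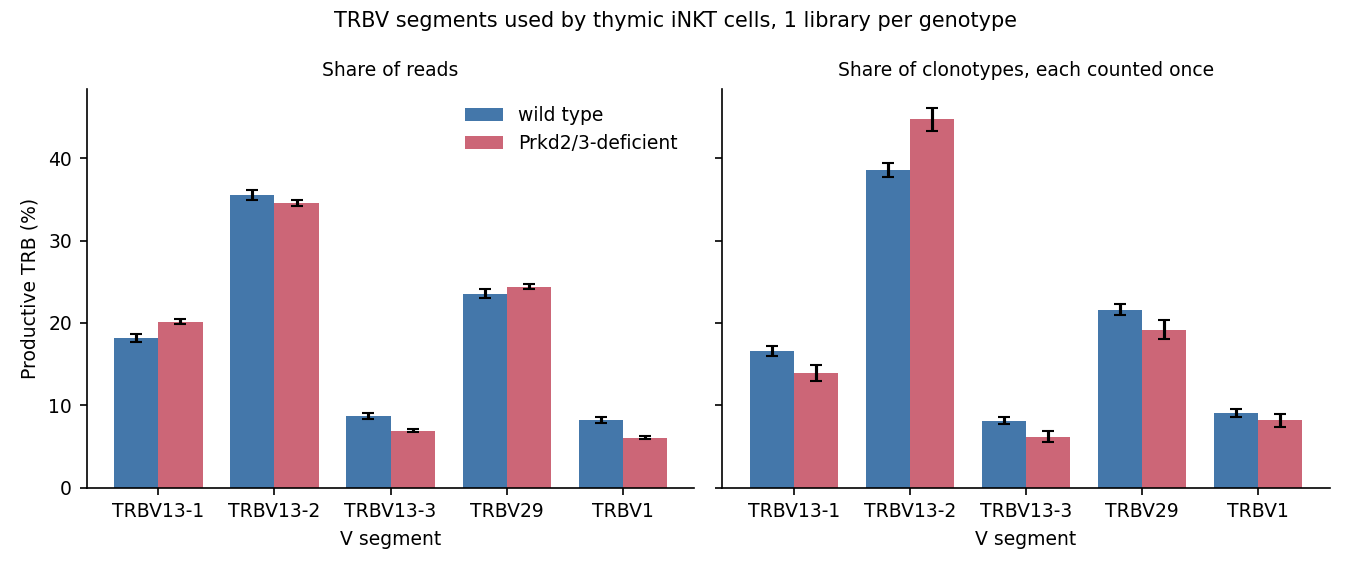
Shares of 5 TRBV segments among productive TRB reads (left) and among productive TRB clonotypes each counted once (right), in percent, for 1 library of each genotype; error bars are exact binomial 95% intervals and cover counting error only. TRBV13-2 was lower in the Prkd2/3-deficient library by reads (34.6% against 35.5%) and higher by clonotypes (44.7% against 38.6%), but not at equal reads per clonotype (38.1% against 38.6%, not plotted); by reads it was higher when single-read clonotypes were left out (34.4% against 32.2%, not plotted).

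No other TRBV or TRBJ segment met the rule for naming, which asked for at least 1% of reads in a library, a 1.5-fold difference, intervals that do not overlap, and the same direction by clonotypes. J beta use was similar in outline. TRBJ2-7 was the most used segment in both libraries, at 20.4% (19.9 to 20.9) of wild-type and 22.6% (22.2 to 22.9) of Prkd2/3-deficient reads, followed by TRBJ2-1 at 12.4% and 13.0%. The TRBJ1 cluster took 39.1% (38.4 to 39.7) and 36.4% (36.0 to 36.7). TRBV17, chosen after its values were seen, had 0.974% (0.854 to 1.11) of wild-type and 2.38% (2.27 to 2.50) of Prkd2/3-deficient reads, but 0.864% and 0.719% of clonotypes. In the Prkd2/3-deficient library 1 TRBV17 clonotype, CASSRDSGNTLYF, held 45.5% of the segment's 1590 reads.

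The beta chain repertoire of the Prkd2/3-deficient library held fewer clonotypes, and its reads were spread less evenly over them. At an equal depth of 24133 productive TRB reads, the wild-type library held 14236 clonotypes and the Prkd2/3-deficient library a mean of 4181 over 100 draws (range 4124 to 4229), 0.294 times as many. Shannon entropy at this depth was 9.39 in wild type and 7.85 in the Prkd2/3-deficient library, and the inverse Simpson index was 9396 against 1274. Clonality, 0 for a fully even repertoire, was 0.0185 and 0.0590. Wild type had 1.70 reads per productive TRB clonotype, and 59.7% of its clonotypes had a single read. Counts this shallow lean towards full evenness, so these values do not show that the wild-type clones themselves were more even. When single-read clonotypes were left out first, the ratio of clonotypes rose to 0.624. The protocols give the input as a range of 10000 to 100000 cells with no number per library, so the cell input behind each count is unknown here.

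**Figure D2:**
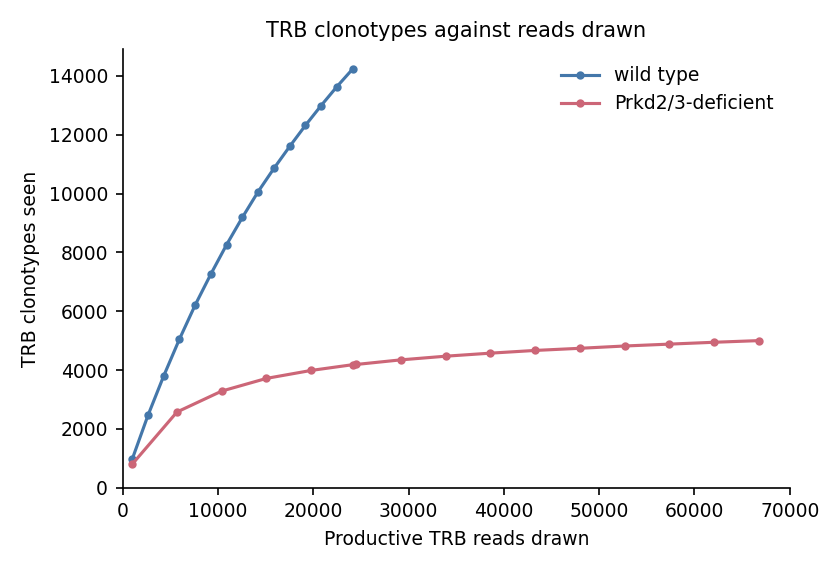
Number of productive TRB clonotypes (y axis) seen in random draws of increasing numbers of productive TRB reads (x axis), as means of 10 draws, for 1 library of each genotype. At 24133 reads the wild-type curve reached 14236 clonotypes and was still rising, while the Prkd2/3-deficient curve rose more slowly, from 4185 clonotypes at that depth to 5004 clonotypes at 66759 reads.

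The 10 most abundant TRB clonotypes took 0.829% (0.718 to 0.951) of productive TRB reads in wild type and 5.07% (4.90 to 5.24) in the Prkd2/3-deficient library. The 5 most abundant Prkd2/3-deficient clonotypes were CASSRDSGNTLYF (TRBV17, 724 reads, 1.08%), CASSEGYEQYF (TRBV13-1, 621 reads, 0.930%), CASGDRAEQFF (TRBV13-2, 499 reads, 0.747%), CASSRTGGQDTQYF (TRBV17, 275 reads, 0.412%) and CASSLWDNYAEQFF (TRBV29, 262 reads, 0.392%). The wild-type ones were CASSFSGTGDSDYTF (TRBV29, 40 reads, 0.166%), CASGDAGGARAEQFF (TRBV13-2, 25 reads, 0.104%), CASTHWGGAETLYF (TRBV13-3, 24 reads, 0.0994%), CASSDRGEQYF (TRBV13-1, 22 reads, 0.0912%) and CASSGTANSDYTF (TRBV13-1, 20 reads, 0.0829%). No clonotype passed 1% of reads in both libraries.

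CDR3 beta length averaged 14.1 amino acids (SD 1.52 over 14236 clonotypes) in wild type and 14.1 (SD 1.52 over 5004 clonotypes) in the Prkd2/3-deficient library. The difference of these means, Prkd2/3-deficient minus wild type, was -0.0262 amino acids, with a 95% interval over clonotypes of -0.0752 to 0.0229 that included 0. Weighted by reads it was -0.154 amino acids (13.9 against 14.1), and at equal reads per clonotype, an alternative added after the data were seen, -0.101 (range over 100 draws -0.161 to -0.0513). Within TRBV13-2 the difference by clonotypes was -0.124 amino acids, with an interval of -0.198 to -0.0488 that excluded 0, and by reads -0.266. The intervals of the other 4 listed segments included 0. By V segment, TRBV13-3 had the shortest mean of the 5 listed segments, 13.6 and 13.5 amino acids, and TRBV1 the longest, 14.4 in both. Between the libraries 387 TRB clonotypes were shared by amino acid CDR3, V and J, which was 2.85% (2.58 to 3.14) of the wild-type and 8.12% (7.36 to 8.93) of the Prkd2/3-deficient amino acid clonotypes. Of these, 241 (62.3%) used TRBV13-2, which made up 44.0% of all Prkd2/3-deficient amino acid clonotypes. By nucleotide sequence 106 were shared.

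Chains of other T cells that the sort could hold were then examined. The MAIT chain, TRAV1-TRAJ33, had 1 read of 97266 in wild type and 0 of 108722 in the Prkd2/3-deficient library, which allows a share of up to 0.00276%. No TRG or immunoglobulin segment was listed, which says nothing of such cells, since the kit amplifies alpha and beta chains. TRDV segments, all joined to TRAJ, had 4 wild-type reads in 3 clonotypes and 66 Prkd2/3-deficient reads in 4. TRBV segments outside the iNKT list took 5.77% (5.48 to 6.07) of wild-type and 7.90% (7.70 to 8.11) of Prkd2/3-deficient TRB reads. Productive TRA chains other than TRAV11-TRAJ18 took 2.03% (1.95 to 2.13) and 2.54% (2.45 to 2.64) of productive TRA reads. With each clonotype counted once they took 95.3% (93.6 to 96.6) and 92.2% (88.2 to 95.2) of productive TRA clonotypes. That difference, -3.11 percentage points, had an interval of -7.24 to 0.0504 that included 0, so no direction was settled by clonotypes. Of the non-invariant reads, 15.9% in wild type and 15.5% in the Prkd2/3-deficient library still used TRAV11. TRAJ18 took 5.05% and 3.22%, and a CDR3 with TRAJ18 followed by TRAJ17 took 4.55% and 5.21%. The last of these holds all of TRAJ18 as well as TRAJ17, so it need not mark another T cell. The cells these chains came from were not determined.

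The TRAV13 family joined to TRAJ50, the chain of V alpha 10 NKT cells, which also recognise CD1d-presented glycolipids, was higher in the Prkd2/3-deficient library. It had 89 of 2765 non-invariant productive TRA reads there, 3.22% (2.59 to 3.95), against 2 of 1979 in wild type, 0.101% (0.0122 to 0.365), a ratio of 31.9 (exact interval 8.56 to 267). By clonotypes it was 6 of 236 against 1 of 810. All these clonotypes had a CDR3 of 13 amino acids, and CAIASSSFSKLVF occurred in both libraries, with 2 wild-type and 5 Prkd2/3-deficient reads.

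The position of J alpha segments along the TRA locus was compared among the non-invariant productive TRA reads, since 5' segments are joined early and 3' segments late. Segments of the 5' group, TRAJ61 to TRAJ40, took 1.97% (1.41 to 2.68) of wild-type and 7.70% (6.74 to 8.76) of Prkd2/3-deficient reads, and 3.33% (2.21 to 4.81) and 10.2% (6.63 to 14.8) of clonotypes. TRAJ50 supplied 109 of the 213 Prkd2/3-deficient reads of this group. The middle group, TRAJ39 to TRAJ21, took 59.2% (57.0 to 61.4) and 57.0% (55.1 to 58.8) of reads, and the 3' group, TRAJ20 to TRAJ1, 38.8% (36.7 to 41.0) and 35.3% (33.6 to 37.1). The 3' group took 36.4% (33.1 to 39.8) and 31.8% (25.9 to 38.1) of clonotypes. The intervals of the middle and of the 3' group overlapped, by reads and by clonotypes. The 3' difference was -3.47 percentage points by reads, with an interval of -6.26 to -0.689 that excluded 0, and -4.64 by clonotypes, with an interval of -11.2 to 2.35 that did not. If the wild-type TRAJ18 clonotypes called TRAV11N first were all counted as non-invariant, the 3' group rose to 95.6% of wild-type reads.

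**Figure D3:**
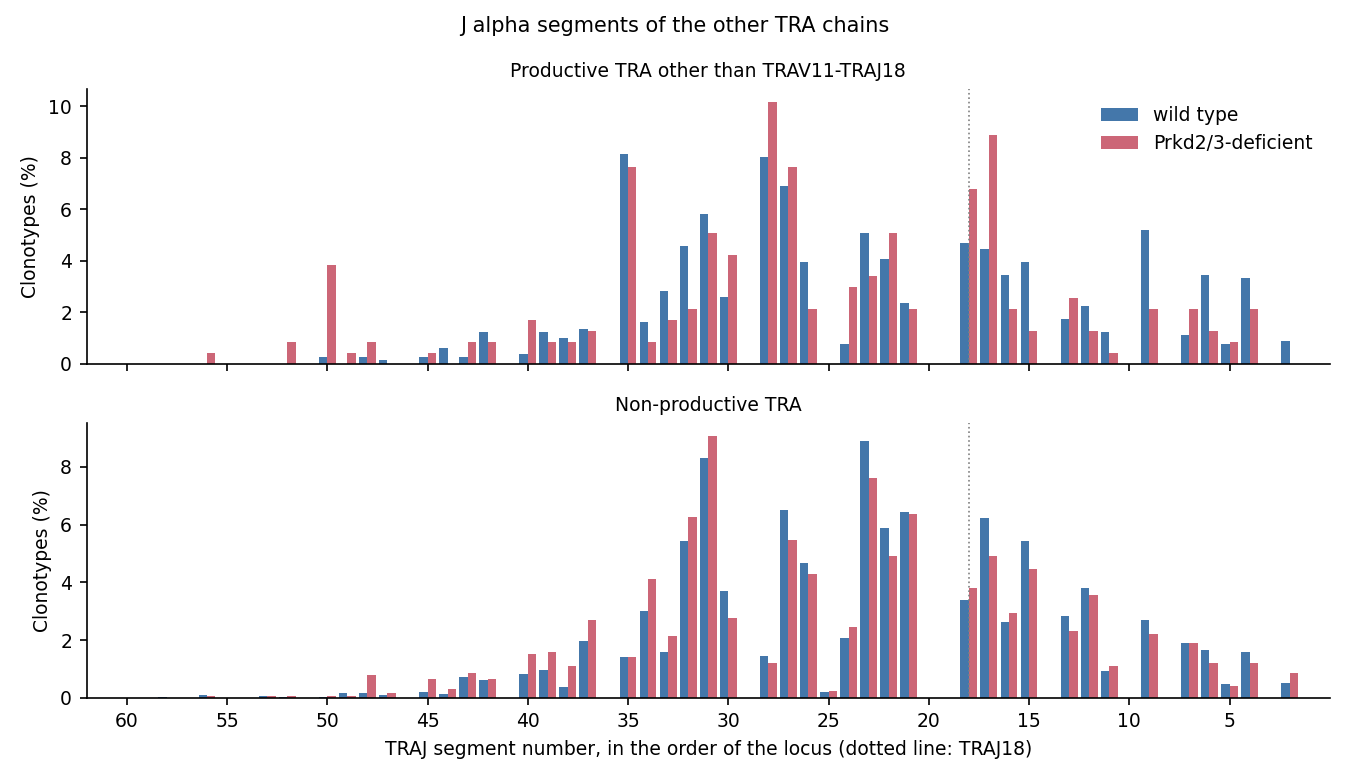
Share of clonotypes, in percent, that use each TRAJ segment, with segments in the order of the locus from TRAJ61 to TRAJ1, for productive TRA other than TRAV11-TRAJ18 (top) and for non-productive TRA (bottom), in 1 library of each genotype; the dotted line marks TRAJ18. In the top panel TRAJ35 to TRAJ9 held 83.6% of wild-type and 80.5% of Prkd2/3-deficient clonotypes, and the 5' group had 3.33% of wild-type and 10.2% of Prkd2/3-deficient clonotypes.

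The naming rule was met by 14 of 40 non-invariant J alpha and 12 of 85 non-invariant V alpha segments, of which the 8 largest ratios of each kind are given. TRAJ50 had 3.94% of Prkd2/3-deficient against 0.152% of wild-type reads, a ratio of 26.0 (8.67 to 128). TRAJ40 (1.30% against 0.253%), TRAJ24 (3.15% against 0.657%) and TRAJ7 (4.92% against 1.26%) were also higher in the Prkd2/3-deficient library. TRAJ26 (0.976% against 4.04%), TRAJ9 (1.05% against 4.24%), TRAJ34 (0.579% against 1.41%) and TRAJ6 (1.41% against 3.39%) were lower there. Among non-invariant V alpha segments, TRAV12D-3 had 143 Prkd2/3-deficient reads in 6 clonotypes and none in wild type, at least 34.1-fold higher against the 3 reads that a count of 0 allows. TRAV7N-6 had 93 reads in 1 clonotype and none in wild type, at least 22.2-fold higher. TRAV5-4 had 1.59% against 0.0505%, a ratio of 31.5 (5.37 to 1272). TRAV1 (2.50% against 0.606%), TRAV15D-2-DV6D-2 (2.39% against 0.657%) and TRAV4N-3 (1.16% against 0.354%) were higher, and TRAV7N-4 (0.181% against 1.87%) and TRAV13N-4 (0.362% against 1.21%) lower, in the Prkd2/3-deficient library. D and N copies of a TRAV segment are near-identical, so the copy named is uncertain. With copies joined, an alternative added after the data were seen, the ratios were 8.92 (5.07 to 17.1) for TRAV12-3, 69.4 (12.2 to 2770) for TRAV7-6 with 1 wild-type read, 10.7 (3.45 to 54.0) for TRAV5-4 and 2.86 (1.29 to 7.19) for TRAV4-3. They were 0.155 (0.0623 to 0.338) for TRAV7-4, 0.583 (0.317 to 1.06) for TRAV13-4 and 1.27 (0.930 to 1.74) for TRAV15-2-DV6-2, so that the last pair no longer excluded a ratio of 1. Copies were joined by name, which left TRAV13-4-DV7, with 12 reads in each library, apart from TRAV13-4. It also left TRAV15N-2, with 8 wild-type and 15 Prkd2/3-deficient reads, apart from TRAV15-2-DV6-2. The named segments rest on few clonotypes, 236 in all in the Prkd2/3-deficient library. TRAV15D-2-DV6D-2 had 3 clonotypes in each library, and TRAV4N-3 had 2 in the Prkd2/3-deficient library and 4 in wild type. By clonotypes, the intervals of the 2 libraries were apart only for TRAJ50, TRAV12D-3, TRAV5-4 and TRAV1 among the named segments.

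Non-productive rearrangements, which have a CDR3 out of frame or with a stop, were kept in the files. They took 7.88% (7.72 to 8.05) of wild-type and 9.37% (9.21 to 9.54) of Prkd2/3-deficient TRA reads, but 84.5% (83.5 to 85.5) and 83.1% (81.1 to 85.0) of TRA clonotypes. Of TRB reads they took 4.21% (3.96 to 4.46) and 4.43% (4.28 to 4.59), with overlapping intervals. Of TRB clonotypes they took 4.80% and 10.2%, with intervals that did not overlap. Clonotype shares depend on sampling, which differed: 71.3% of wild-type and 38.1% of Prkd2/3-deficient non-productive TRB clonotypes had a single read.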

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

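Alternatives chosen after the data were seen were the wider rule for TRAV11 calls, the narrower rule for non-invariant chains, the joined TRAV copies and the thinning to equal reads per clonotype; the others were fixed before. Of 65 alternatives over 25 results, 32 stayed within the counting interval, the spread of draws, the interval of the difference in mean CDR3 length or 1.5-fold for counts. Another 24 left it in the same direction or without a settled direction, and 9 changed sign, 2 of them with an interval that included 0. No paired analysis was possible because each genotype has 1 library. Differences are Prkd2/3-deficient minus wild type in percentage points, and unless stated the cause was not tested.

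The difference in the invariant TRA share was 26.1 by the first segment named and -0.509 when TRAV11 or TRAV11D anywhere in the call counted. This was almost entirely because 1 abundant wild-type clonotype was called TRAV11N first. By the first segment named it was 3.69 with each clonotype once, 22.6 with non-productive chains and 25.0 for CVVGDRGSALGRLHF only; under the wider rule these were 3.11, -1.90 and -1.52. Leaving out calls with several segments gave no value, since no invariant read was left. By the narrower rule, the differences in the 5', middle and 3' TRAJ groups were 7.56, 52.7 and -60.3. Without any TRAV11, TRAV11D or TRAJ18 read, the 3' difference was -6.32.

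Counting each clonotype once turned TRBV13-2 to 6.13 and TRBV29 to -2.44. It changed the sign of non-invariant TRA, to -3.11 (-7.24 to 0.0504), and of non-productive TRA, to -1.40 (-3.58 to 0.652), but these intervals included 0 and their direction is not settled. It moved TRBV1 to -0.937, TRAV1-TRAJ33 to -0.118, TRAV13 family-TRAJ50 to 2.42 and non-productive TRB to 5.38. Leaving out single-read clonotypes turned TRBV13-2 to 2.17 and TRBV29 to -1.23, and moved TRBV1 to -1.24. At equal reads per clonotype, the TRBV29 difference in clonotypes was 1.58. Without the most abundant clonotype, the 5 listed TRBV segments differed by -1.11. Joining copies moved TRAV15D-2-DV6D-2 to 0.896.

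The ratio of TRB clonotypes was 0.299 by amino acid CDR3, 0.624 without single-read clonotypes and 0.352 unthinned, each below 1. The 100 most abundant clonotypes differed by 12.1. The difference in mean CDR3 beta length, -0.0262 amino acids, was -0.154 weighted by reads and -0.101 at equal reads per clonotype. Shared clonotypes numbered 106 by nucleotide sequence and 193 without single-read clonotypes. Depth limits the wild-type TRB values, at 1.70 reads per productive clonotype against 13.3.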

Other observations

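The comparison of clonotypes at equal reads was planned before the data were examined, though the bound it is held to was set after its value was seen, and the thinning to equal reads per clonotype was chosen before its result was seen; the tests of single-mismatch errors, input, single-read clonotypes and a single expanded clone were chosen after.

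Within the TRAV11-TRAJ18 chains, the residue at the V-J junction varied in both libraries. Alanine in place of glycine took 2.11% (2.02 to 2.20) of wild-type and 2.15% (2.07 to 2.24) of Prkd2/3-deficient reads with this CDR3 framework, each in 1 nucleotide sequence, and isoleucine 0.159% and 0.190%. Valine was found in 910 Prkd2/3-deficient reads of 1 nucleotide sequence, 0.859% (0.804 to 0.917), and in none of 95226 wild-type reads. Serine had 66 wild-type reads in 5 nucleotide sequences and 1 Prkd2/3-deficient read, and glutamine 10 wild-type and 188 Prkd2/3-deficient reads. A further CDR3, with all of TRAJ18 followed by TRAJ17, had 90 wild-type and 144 Prkd2/3-deficient reads and made up 4.55% and 5.21% of the non-invariant productive TRA reads.

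Non-productive TRA clonotypes, which encode no receptor chain, were counted on both sides of TRAJ18. There were 3059 upstream and 1419 downstream in wild type, and 870 and 341 in the Prkd2/3-deficient library. These counts were not set against the number of TRAJ segments on each side, so no preference in position is drawn from them. The median TRAJ number was 23 over 4635 wild-type clonotypes and 24 over 1259 Prkd2/3-deficient ones. The 5' group took 3.15% (2.67 to 3.69) and 5.32% (4.15 to 6.71) of these clonotypes, and the 3' group 34.0% (32.6 to 35.4) and 30.9% (28.4 to 33.5), a difference of -3.10 percentage points (interval -5.95 to -0.169). By reads the 3' group took 33.1% and 28.0%. TRBV13-2 clonotypes began with CASGD in 55.5% (54.1 to 56.8) of wild-type and 56.0% (54.0 to 58.1) of Prkd2/3-deficient cases, while by reads the shares were 55.5% (54.5 to 56.6) and 62.1% (61.4 to 62.7). The shared TRB clonotypes had a mean CDR3 length of 13.4 amino acids, against 14.2 over all wild-type and 14.1 over all Prkd2/3-deficient amino acid clonotypes.

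The Prkd2/3-deficient library held fewer TRB clonotypes. A lower number of reads is argued against, since that library had more productive TRB reads, 66759 against 24133. The ratio at equal reads was 0.294 and at most 0.297 in any draw. Thinning the library with fewer clonotypes could only lower the unthinned ratio of 0.352, so this comparison adds no support. Single-mismatch errors of clonotypes seen with more reads are argued against: 5.65% of wild-type clonotypes lay 1 mismatch from a more abundant one. To close the gap 70.6% would have to go. The count misses an error whose source had no more reads than itself, and the wild-type median was 1 read. Among single-read clonotypes the share was 7.23% in wild type and 60.8% in the Prkd2/3-deficient library. Fewer cells or RNA molecules in that library cannot be told apart from a smaller repertoire, because the stated input range spans 10-fold and the gap is 3.40-fold. The lower count was not limited to TRB. Non-productive TRA clonotypes numbered 4635 in wild type and 1259 in the Prkd2/3-deficient library, and non-invariant productive TRA clonotypes 810 and 236. Both TRA sets had more reads in the Prkd2/3-deficient library. A smaller or more expanded repertoire in the absence of Prkd2 and Prkd3 was not tested and stays open.

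TRBV13-2 took a larger share of Prkd2/3-deficient clonotypes, 44.7% against 38.6%. Single-read clonotypes with errors are argued against, since without those of the Prkd2/3-deficient library its share was still 43.8% (42.3 to 45.3), above the midpoint of 41.6% between the libraries. Thinned to the wild-type number of reads per clonotype, the Prkd2/3-deficient share fell to 38.1% (36.3 to 39.7 over 100 draws), below the wild-type upper bound of 39.4%. Such thinning draws a clonotype share towards the share by reads, so a fall was bound to occur and does not decide for this cause. More complete sampling of clonotypes with few reads stays a candidate explanation for the whole gap. A genotype effect was not tested.

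TRAV13 family-TRAJ50 reads were more frequent in the Prkd2/3-deficient library. A single expanded clone or PCR jackpot is argued against, as the most abundant of 6 nucleotide sequences held 27.0% of the reads. More complete sampling is not excluded. At the wild-type reads per non-invariant clonotype, the Prkd2/3-deficient share of clonotypes was 3.54% (1.55 to 5.04 over 100 draws). The wild-type upper bound was 0.686%. The share by reads, 3.22%, and the unthinned share of clonotypes, 2.54%, both lay above that bound. Thinning draws a clonotype share towards the share by reads, so a mean above the bound was bound to occur and does not decide. The thinned share rested on 2 to 6 clonotypes. The interval of the ratio excluded 1 in 99 draws, where all were required. TRAJ50 was also joined to TRAV7-5 in 13 Prkd2/3-deficient reads with the CDR3 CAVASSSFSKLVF and to TRAV12-3 in 6, while the TRAV13 family as a whole took 14.7% of non-invariant reads there against 16.2% in wild type. More V alpha 10 NKT cells and a sort that let more of them through were not tested and stay open. A wider shift of TRAJ use towards the 5' segments, which were also higher among non-productive chains, was not tested either and stays open. TRAJ50 itself had 1 non-productive clonotype in each library, with 2 of 8323 wild-type and 13 of 11242 Prkd2/3-deficient reads, too few to weigh.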
